A study of Mus musculus with 12 samples.

How the data were processed

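Gene expression was measured in 12 samples of mouse embryonic stem cell progenitors, 3 arrays for each of 4 sorted populations. Per the labels, biotinylated cRNA was made from 5 ug of total RNA per array. Groups were taken from the sample titles, since 1 population is misprinted in the description of the sort. The deposited values are probe set intensity values on a linear scale, not log2 values, 1 per probe set and array. Per the labels the authors used MAS5, with no version or scaling target. The values have a common floor just above 2 units (the lowest was 2.09), and their trimmed means ran from 22.3 to 23.9 (ratio 1.08) instead of being equal, so the method that made them stays open. There are no detection calls, and no genome coordinates are given. The number of arrays, 3 per group, limits the precision.

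The table held 45101 probe sets, of which 64 controls were left out. The platform annotation listed genes for 35877 probe sets. Of these 932 with several genes were left out, and 34945 had 1 gene. A further 9160 listed no gene. Symbols were updated through Entrez gene IDs, apart from 204 that had no current entry. Each of 18193 genes was represented by its probe set with the highest mean over the 12 arrays. Values were used as log2(intensity + 4.10), the pseudocount being the 25th percentile of all values, with no further normalization. Genes with a mean under the 40th percentile of all probe sets (3.22 on the log2 scale) were left out, which left 13698.

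Models were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) to all 12 arrays with 1 mean per group and 8 residual degrees of freedom. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. The 6 pairwise comparisons, the F-test and the interaction were each adjusted by Benjamini-Hochberg over the genes tested, with a threshold of 0.05 and no minimum fold. All tests but the F-test were two-sided. With 3 arrays against 3, an exact permutation test of a single gene cannot give a p below 0.1, and the arrays of both groups fail to overlap by chance for 10% of genes.

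A set of 24 gene lists was tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists, with camera at an estimated correlation and fry beside it. The lists covered reporter-linked, core cardiac, second and first heart field, sarcomere, calcium handling, smooth muscle, endothelial, blood, pluripotency, primitive streak, endoderm, neural, paraxial, mesenchyme, epicardial and cell cycle genes. They also covered BMP, Wnt, Notch and FGF pathway, stress, glycolysis and mitochondrial genes. Groups, comparisons, lists, the naming rule and most alternatives were chosen before the data were examined. Named in each comparison were Nkx2-5, Mef2c and Isl1, and the 5 largest increases and 5 largest decreases past the threshold. The latter needed non-overlapping groups and the same sign in each experiment, and 0 genes without a name were passed over. Of a described list up to 4 members with the largest change past the threshold were eligible, and for the F-test and the interaction the 5 smallest adjusted p.

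The experiment letter was checked as a pairing of arrays. Deviations from group means correlated at 0.116 to 0.424 (mean 0.264) in the 18 pairs of arrays of one experiment, and at -0.131 on average across experiments (highest 0.0714). Deviations from a group mean cancel over its arrays, so the average across experiments follows from that within them and is no separate observation. All 12 arrays correlated best with their own experiment in every other group, and 331 genes differed between experiments. A model with the experiment as a block was an alternative, and its values are given where they change a call or move a count by more than 1.5 times. Other alternatives were pseudocounts of 1 and 6.52 (the median), quantile normalization, no filter, a filter at the 60th percentile, every probe set on its own, an intensity trend in the variance, only the 6 arrays compared, a minimum fold, and each array or experiment left out. The fit with an intensity trend also used limma's robust option throughout, and neither was run alone. Counts of list genes, of genes placed between populations and of genes called in 2 comparisons, each with arrays left out, and list tests of the interaction, were chosen after seeing the data.

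The procedure was tested on simulated data for double-positive against double-negative cells, with 200 changed genes among 13698 in each of 20 simulations. It recovered 71.1% of genes changed by 0.5 on the log2 scale, 97.9% at 1 and 100% at 2 and 3, and 5.58% of calls were false. The simulated noise was normal and independent between genes and arrays, with no shift by experiment and no outlying array. The real comparison called 4317 genes, far more than were changed here, so these rates need not hold for the real calls. Of the calls of named genes, 247 could be checked on another probe set of the gene. That probe set passed in the same direction for 136 and in the opposite direction for 0, and for 111 no other probe set passed.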

Results

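Gene expression was measured with 12 single-colour Affymetrix mouse arrays in cells sorted from differentiating mouse embryonic stem cells. The cells came from embryoid bodies on day 6 of differentiation, which are aggregates grown in hanging drops in which stem cells form early embryonic tissues. They carried a red reporter (dsRed) under an enhancer of the second heart field, the progenitor pool of the outflow tract and right ventricle, and a green reporter (eGFP) under a cardiac-specific enhancer. Flow sorting on the reporters gave 4 populations: double-positive, red-only, green-only and double-negative cells. Each population was hybridised to 3 arrays, 1 from each of experiments A, B and C. The labels do not state whether these are separate differentiation cultures, nor whether the 4 populations of one letter came from one sort, so it is unknown whether the spread of 3 arrays includes that between cultures. Values are probe set intensities in linear units, and an array has no read depth. Their number, 3 arrays per population, limits the precision. The array medians lay between 6.29 and 6.73 intensity units, and single values ran from 2.09 to 8820. Probe set annotation lists neither reporter transcript, so the sort was not checked on the reporters themselves. Group values below are means ± SD of 3 arrays in intensity units, and log2 fold changes carry the standard error (SE) of the model.

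The arrays grouped first by population. Pearson correlations of log2 values across genes were 0.980 to 0.995 between arrays of one population and 0.924 to 0.988 between arrays of different populations, across genes that are not independent replicates. Principal component 1, with 56.5% of the variance, ordered double-negative arrays (36.6 to 39.3), red-only arrays (-5.22 to -0.893), and double-positive arrays (-29.9 to -24.6), with green-only arrays between -13.2 and 2.06. Component 2 (15.1%) set the red-only arrays, at -23.5 to -16.0, apart from all others, which lay above 0. The green-only array of experiment A stood apart on component 3 (9.45%), at -26.1. Its genes also deviated most from their group means, with an SD of 0.192 on the log2 scale against 0.102 to 0.150 for the other 11 arrays. A control for RNA quality, the ratio of 3' to 5' actin signal, was higher in double-positive (1.55, 1.47 and 1.40 in experiments A, B and C) than in green-only (1.35, 1.44 and 1.33) and double-negative arrays (1.36 in A and B and 1.34 in C) of each experiment, and than in red-only arrays (1.40, 1.48 and 1.32) in A and C. Double-positive A had the highest actin ratio and the highest 18S RNA control signal (793.5, with 462.7 the next), while its Gapdh ratio of 0.945 lay within the range of the others (0.883 to 1.01). Among 13698 genes tested with limma, 4429 (32.3%) differed among the populations in an F-test of all 3 independent contrasts.

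**Figure D1:**
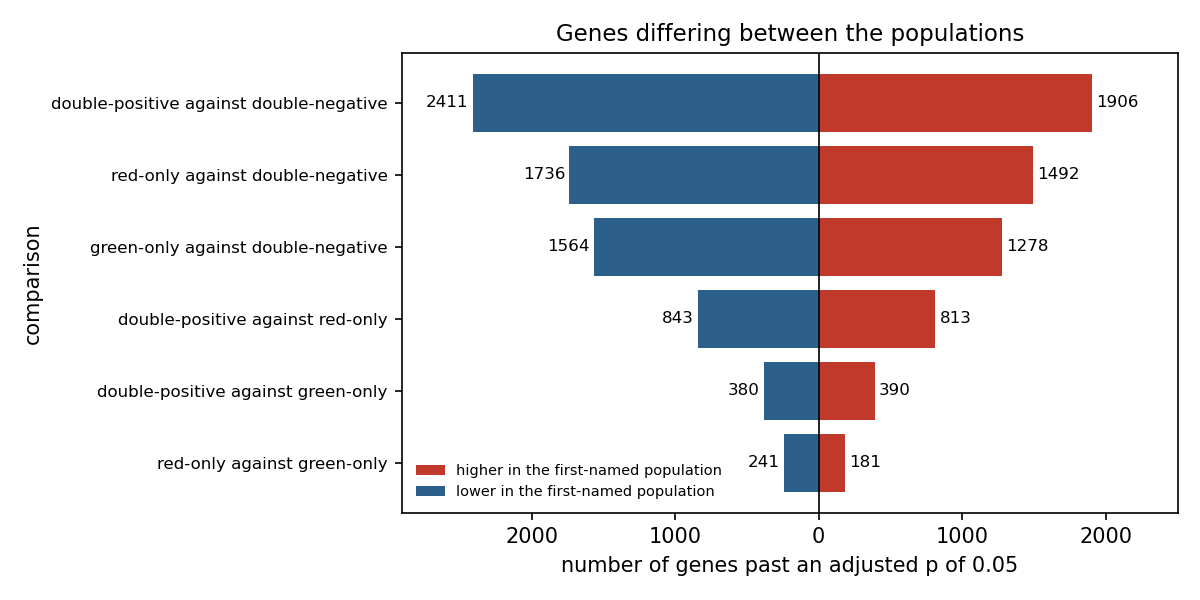
Genes past a Benjamini-Hochberg adjusted p of 0.05 in each pairwise comparison (horizontal axis, number of genes; higher and lower drawn apart, with the comparison on the vertical axis). Each comparison with double-negative cells called at least 2842 genes and each comparison among the reporter-positive populations at most 1656.

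The genes of the reporter-linked list, Nkx2-5, Mef2c and Isl1, were higher in each reporter-positive population than in double-negative cells. Because the cells were sorted on reporters under heart enhancers, higher levels of these genes may follow from the sort itself. Nkx2-5, a cardiac transcription factor, averaged 415 ± 42 in double-positive, 232 ± 38 in green-only, 166 ± 36 in red-only and 35.5 ± 3.4 in double-negative cells. Mef2c averaged 458 ± 26 in double-positive, 236 ± 42 in red-only and 231 ± 65 in green-only cells, against 21.6 ± 6.7 in double-negative cells. Isl1, a second heart field transcription factor, averaged 101 ± 5.6 in red-only, 86.7 ± 9.5 in double-positive, 80.5 ± 7.9 in green-only and 44.5 ± 9.0 in double-negative cells. The 5 genes with the smallest adjusted p in the F-test were Myocd (2.62e-09), Tnni1 (2.62e-09), Myl7 (3.85e-09), Tnnt2 (3.85e-09) and Utf1 (3.85e-09). Myocd, which codes for a coactivator of muscle genes, averaged 228 ± 18 in double-positive, 111 ± 4.4 in green-only, 87.2 ± 7.7 in red-only and 10.2 ± 2.6 in double-negative cells. Utf1, a pluripotency gene, averaged 334 ± 58 in double-negative cells and 40 ± 0.75, 44.3 ± 3.6 and 42.1 ± 2.5 in double-positive, red-only and green-only cells.

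**Figure D2:**
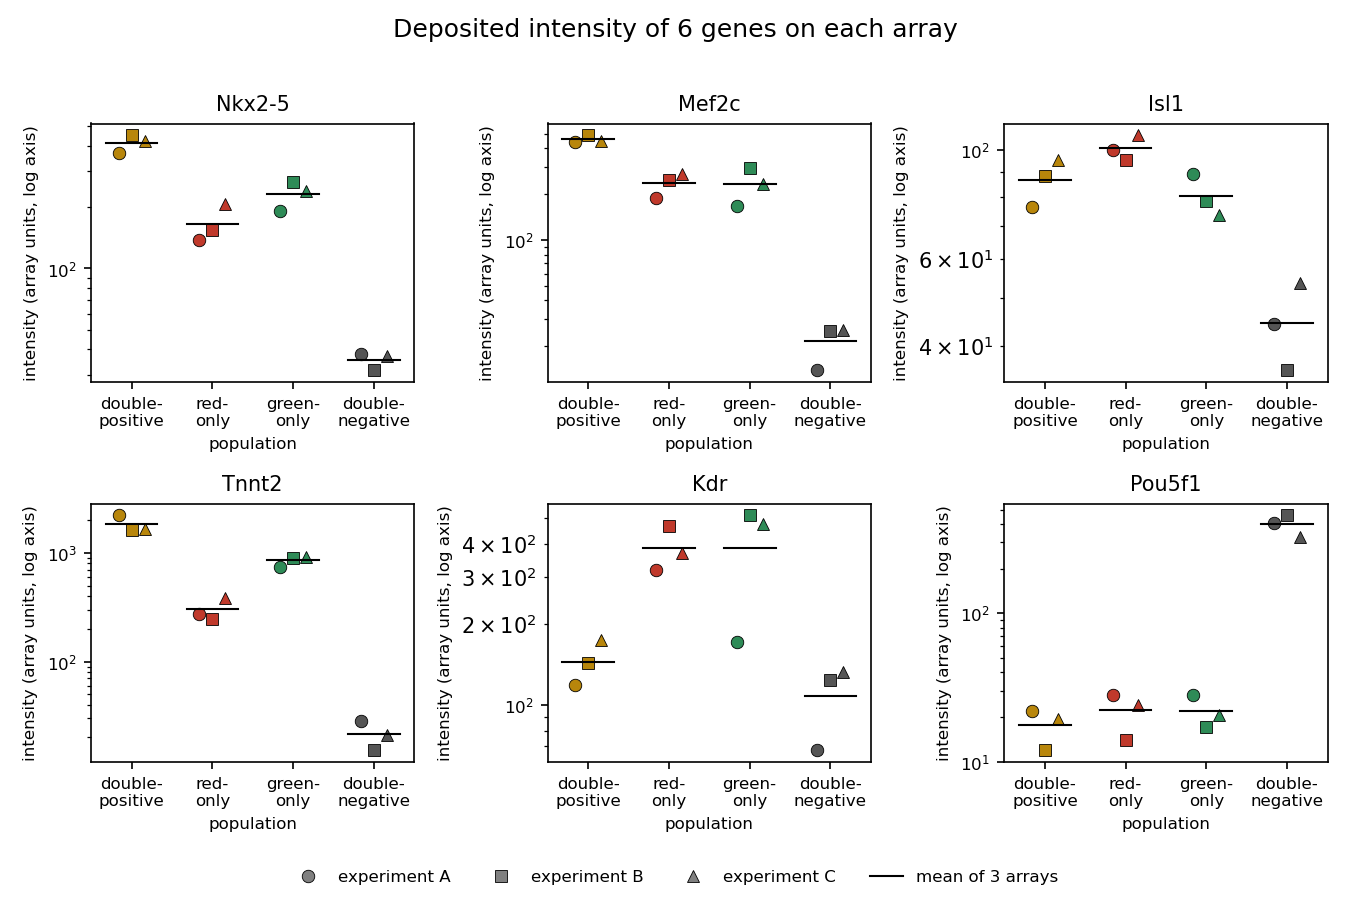
Intensity of 6 genes on each of the 12 arrays (vertical axis, log scale; points are arrays and bars the mean of 3 arrays of a population). Nkx2-5 was 415 ± 42 in double-positive and 35.5 ± 3.4 in double-negative cells, with both single-reporter populations between them.

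Double-positive and double-negative cells were compared to ask which genes mark cells with both cardiac reporters. Of 13698 genes, 4317 (31.5%) differed, 1906 higher and 2411 lower in double-positive cells. The 5 largest increases were Tnnt2 (1830 ± 340 against 21.6 ± 6.7; log2 fold change 6.17 ± 0.20 SE, adjusted p = 7.56e-10), Myh6 (5.87 ± 0.26, adjusted p = 8.03e-09), Myl3 (5.85 ± 0.34, adjusted p = 5.63e-08), Myl2 (5.84 ± 0.28, adjusted p = 1.04e-08) and Myl4 (5.78 ± 0.23, adjusted p = 4.08e-09). All 5 code for proteins of the sarcomere. The 5 largest decreases were the embryonic globin genes Hbb-bh1 (26.6 ± 19 against 793 ± 310; -4.81 ± 0.45, adjusted p = 4.07e-06), Hbb-y (-4.25 ± 0.18, adjusted p = 6.88e-09) and Hba-x (-3.95 ± 0.31, adjusted p = 8.24e-07), and the pluripotency genes Pou5f1 (17.7 ± 5.2 against 398 ± 64; -4.22 ± 0.23, adjusted p = 3.04e-08) and Dppa5a (-3.98 ± 0.18, adjusted p = 9.20e-09). The probe sets of Tnnt2, Hbb-y (_x_at) and Myl3 (_s_at) share probes with related transcripts, so part of their signal can come from other family members. Hbb-y in double-positive cells lay under every array median, so the size of its change is uncertain, from -4.90 to -3.90 with other pseudocounts. Nkx2-5 was higher by 3.40 ± 0.15, Mef2c by 4.20 ± 0.22 and Isl1 by 0.91 ± 0.13 (adjusted p = 8.14e-09, 2.14e-08 and 0.000114). In all such lists of the largest changes, the 3 arrays of one population lay above the 3 of the other, and the difference had one sign in each experiment.

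Cardiac gene lists were higher in double-positive than in double-negative cells. All 28 sarcomere and contractile genes were higher (28 adjusted over the list alone), with a median log2 fold change of 4.54 and a camera adjusted p of 2.54e-35. Of 20 core cardiac transcription factors 17 were higher (17 adjusted over the list alone; median 1.30, camera adjusted p = 4.89e-16), led by Smyd1 (4.54 ± 0.20), Mef2c and Myocd (4.03 ± 0.11). Of 18 cardiac calcium handling and ion channel genes 12 were higher (14 adjusted over the list alone; median 0.56, 0.36 without double-positive A, camera adjusted p = 1.97e-07), and 1, the gap junction gene Gja1, was lower (-2.41 ± 0.30). The medians of the 3 reporter-linked genes, of 9 first heart field genes and of 15 second heart field genes were 3.40, 1.26 and 0.47 (camera adjusted p = 4.26e-05, 5.10e-05 and 0.00363). Among second heart field genes Mef2c changed most, followed by Hand2 (3.24 ± 0.23). Among 12 smooth muscle genes the median was 0.45 (0.29 without double-positive A, camera adjusted p = 0.00457), and Acta2 rose most (4.38 ± 0.17). The smooth muscle call did not hold with an estimated inter-gene correlation (adjusted p = 0.253), while the other cardiac calls in this paragraph did. Nkx2-5, Mef2c and Isl1 are also members of the core list and of a heart field list, so these lists are not independent.

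Lists of other tissues and processes also shifted in this comparison, but of these calls only that of pluripotency genes held with an estimated inter-gene correlation (adjusted p = 0.0442). The adjusted p with that estimate were 0.0573 for cell cycle, 0.0673 for mitochondrial, and 0.161 for blood and for BMP pathway genes, and 0.253 to 0.461 for the others called. Of 27 cell cycle genes 25 were lower in double-positive cells (27 adjusted over the list alone; median -0.75, camera adjusted p = 4.45e-15). Of 18 pluripotency genes 11 were lower (12 adjusted over the list alone; median -0.83, camera adjusted p = 1.22e-06), and 2 were higher, a number that was 1 without double-positive B or C or any double-negative array. Of 22 mitochondrial energy metabolism genes 18 were higher (19 adjusted over the list alone; median 0.49, camera adjusted p = 5.62e-10). Of 14 blood genes 5 were lower (7 adjusted over the list alone; median -0.23, camera adjusted p = 0.00221), 3 of them the globin genes named above. BMP pathway, stress and dissociation, and glycolysis genes were higher, with medians of 0.28, 0.43 and 0.41 (camera adjusted p = 0.00177, 0.00443 and 0.00856), and the 0.43 of stress genes was 0.27 without double-positive C. Mesenchyme and matrix genes were higher (median 0.25, camera adjusted p = 0.0196), and endoderm and neural genes lower (medians -0.58 and -0.23, camera adjusted p = 0.0208 for each). Those 3 lists did not pass without the double-negative array of experiment A (0.0552, 0.0926 and 0.0724), and the endoderm median was -0.32 without it and -0.92 without double-negative B. Endothelial genes (median -0.04, camera adjusted p = 0.856), primitive streak and early mesoderm genes (-0.02, 0.323), epicardial genes (0.06, 0.555), Wnt pathway genes (-0.12, 0.323) and Notch pathway genes (-0.24, 0.176) did not pass. Paraxial mesoderm and skeletal muscle genes had a median of 0.11 and a mean of -0.06 (camera adjusted p = 0.604). FGF pathway genes (-0.12, 0.0864) passed only without the double-positive (0.0347) or the green-only (0.0475) array of experiment A, or with no filter on low values (0.0267).

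**Figure D3:**
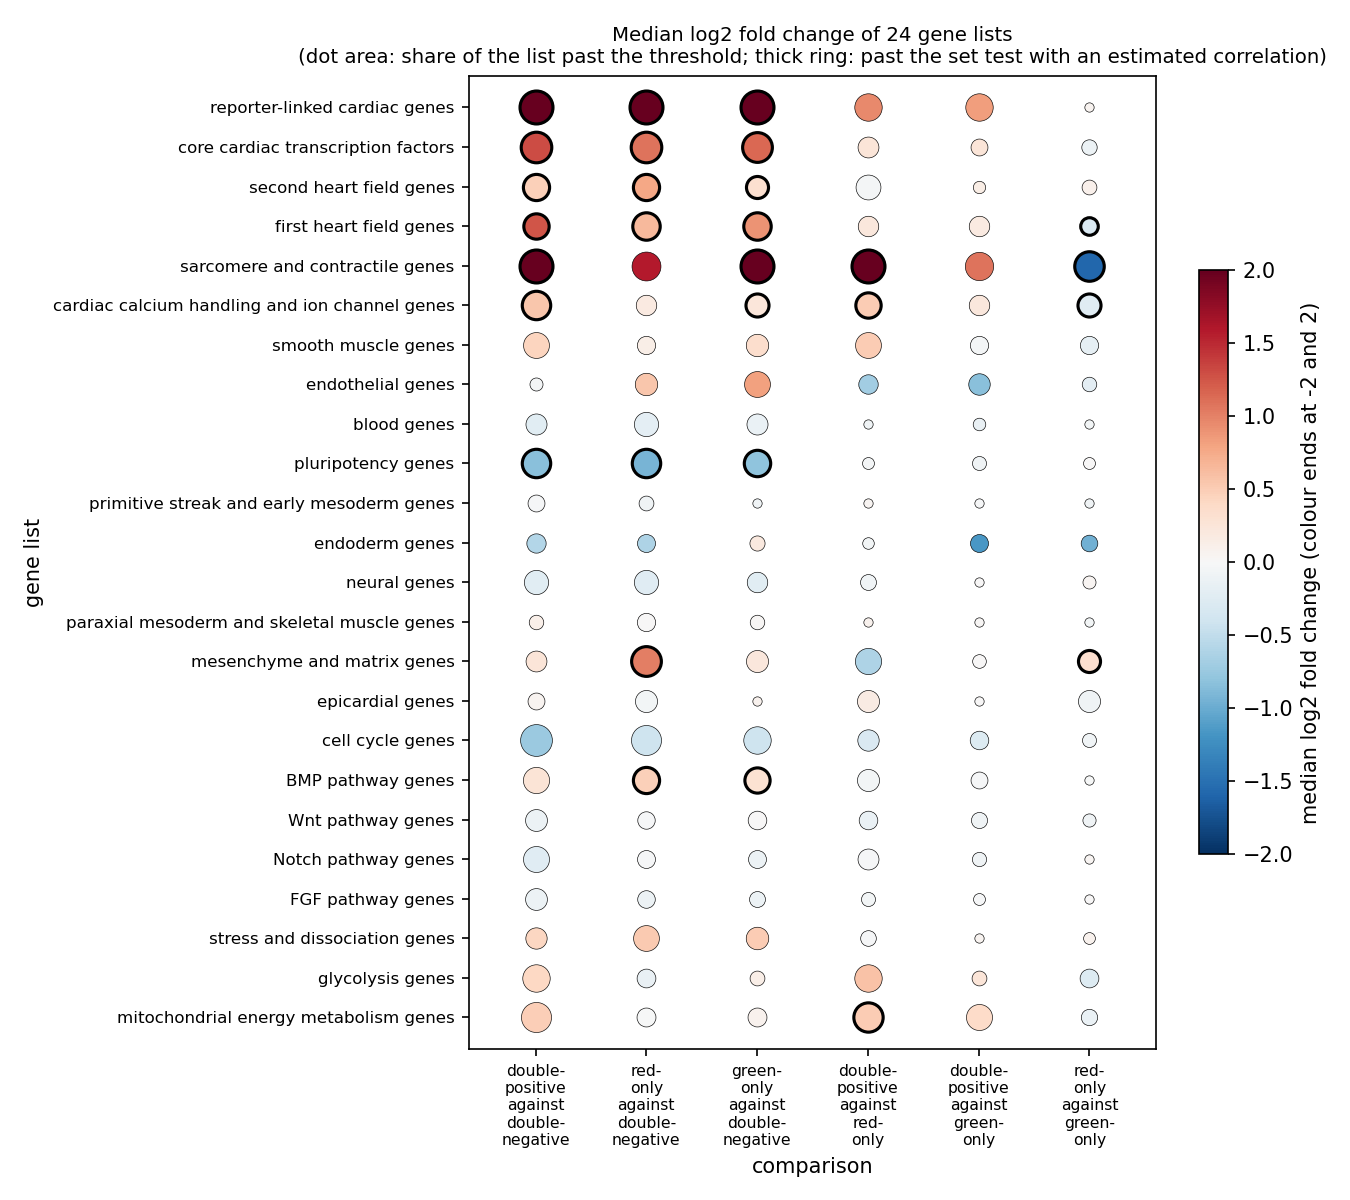
Median log2 fold change of each gene list (vertical axis) in each pairwise comparison (horizontal axis), drawn as a colour scale that ends at -2 and 2, with dot area for the share of the list past the threshold and a thick ring for lists past camera with an estimated correlation. Sarcomere and contractile genes had medians of 4.54, 1.59 and 3.28 in double-positive, red-only and green-only cells against double-negative cells.

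Red-only and double-negative cells were compared to ask which genes mark cells with the second heart field reporter alone. Of 13698 genes 3228 (23.6%) differed, 1492 higher and 1736 lower in red-only cells. The 5 largest increases were Tnnt2 (302 ± 72 against 21.6 ± 6.7; log2 fold change 3.58 ± 0.20 SE, adjusted p = 1.79e-07), Tnni1 (3.42 ± 0.15, adjusted p = 2.70e-08), Myl7 (3.37 ± 0.17, adjusted p = 7.80e-08), Hand2 (224 ± 33 against 19.3 ± 4.1; 3.29 ± 0.23, adjusted p = 9.91e-07) and Mef2c (3.24 ± 0.22, adjusted p = 8.27e-07). The 5 largest decreases were those of the comparison of double-positive cells: Hbb-bh1 (-4.12 ± 0.45, adjusted p = 3.25e-05), Hbb-y (-4.06 ± 0.18, adjusted p = 2.70e-08), Pou5f1 (-3.97 ± 0.23, adjusted p = 2.58e-07), Hba-x (-3.85 ± 0.31, adjusted p = 2.81e-06) and Dppa5a (-3.61 ± 0.18, adjusted p = 8.96e-08). Hbb-y also lay under every array median in red-only cells (-4.59 to -3.75 with other pseudocounts). Nkx2-5 was higher by 2.09 ± 0.15 (adjusted p = 1.40e-06) and Isl1 by 1.12 ± 0.13 (adjusted p = 4.52e-05).

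In red-only cells, core cardiac transcription factors (17 of 20 genes higher, 17 adjusted over the list alone; median 1.09, camera adjusted p = 4.97e-16) and sarcomere and contractile genes (21 of 28, 21 adjusted over the list alone; median 1.59, camera adjusted p = 3.11e-18) exceeded their levels in double-negative cells. With an estimated inter-gene correlation the sarcomere call did not hold (adjusted p = 0.103), nor did those of endothelial (0.375), stress (0.375), calcium handling (0.260) and smooth muscle genes (0.375) given next, while the other calls in this paragraph did. Second heart field genes were higher in 9 of 15 cases (9 adjusted over the list alone; median 0.78, camera adjusted p = 3.72e-07). Mesenchyme and matrix genes were higher in 15 of 20 cases (15 adjusted over the list alone; median 1.03, camera adjusted p = 8.89e-10), with Col5a1 at 2.31 ± 0.16 and Col5a2 at 2.20 ± 0.14. Of 20 BMP pathway genes 12 were higher (13 adjusted over the list alone; median 0.47, camera adjusted p = 9.64e-08). Of 24 endothelial genes 10 were higher (14 adjusted over the list alone, 6 of all genes without the double-negative array of experiment A; median 0.56, camera adjusted p = 1.52e-05). Kdr averaged 385 ± 74 against 108 ± 36 (1.83 ± 0.35, adjusted p = 0.00216) and Etv2 78.8 ± 8.5 against 19.8 ± 2.7 (1.80 ± 0.16, adjusted p = 6.38e-06). Reporter-linked, first heart field and stress and dissociation genes were higher, with medians of 2.09, 0.65 and 0.53 (camera adjusted p = 7.87e-06, 0.00122 and 0.000971). Calcium handling and ion channel genes had a median of 0.18 (camera adjusted p = 0.0270). Smooth muscle genes had a median of 0.14 (camera adjusted p = 0.0270, and 0.0706 without the red-only array of experiment A). That median was 0.24 without red-only B, 0.07 without double-negative B and 0.08 without red-only C.

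Pluripotency genes were lower in red-only than in double-negative cells in 12 of 18 cases (13 adjusted over the list alone; median -0.93, camera adjusted p = 8.89e-10). Cell cycle genes were lower in 22 of 27 cases (24 adjusted over the list alone, 14 of all genes without the red-only array of experiment B; median -0.41, camera adjusted p = 1.12e-10). Blood genes were lower (median -0.20, camera adjusted p = 0.00223). Of the calls in this paragraph only that of pluripotency genes held with an estimated inter-gene correlation, with adjusted p of 0.108 for cell cycle, 0.186 for blood, 0.375 for neural and 0.550 for endoderm genes. Endoderm genes were lower (median -0.62, camera adjusted p = 0.0283), but not past the threshold without the double-negative array of experiment A (0.150) or the red-only array of experiment B (0.0701). Neural genes were lower (median -0.24, camera adjusted p = 0.0270), but not past it without the red-only (0.0602) or the double-negative (0.0886) array of experiment A. Glycolysis genes had a median of -0.15 (camera adjusted p = 0.0590). They passed with the experiment as a block (0.0157), with no filter on low values (0.0398), and without double-positive B (0.0494), double-negative B (0.0258) or red-only C (0.00406).

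Green-only and double-negative cells were compared to ask which genes mark cells with the cardiac-specific reporter alone. Of 13698 genes 2842 (20.7%) differed, 1278 higher and 1564 lower in green-only cells. The 5 largest increases were Tnnt2 (852 ± 97 against 21.6 ± 6.7; log2 fold change 5.09 ± 0.20 SE, adjusted p = 6.44e-09), Myh6 (4.97 ± 0.26, adjusted p = 7.02e-08), Actc1 (4.82 ± 0.25, adjusted p = 6.04e-08), Myl4 (4.75 ± 0.23, adjusted p = 4.00e-08) and Myl3 (4.64 ± 0.34, adjusted p = 1.01e-06). The 5 largest decreases were Hbb-bh1 (-4.03 ± 0.45, adjusted p = 4.07e-05), Pou5f1 (-3.96 ± 0.23, adjusted p = 1.80e-07), Hbb-y (-3.93 ± 0.18, adjusted p = 2.52e-08), Hba-x (-3.81 ± 0.31, adjusted p = 2.44e-06) and Dppa5a (-3.61 ± 0.18, adjusted p = 5.25e-08). Hbb-y in green-only cells lay within the range of the array medians (-4.42 to -3.65 with other pseudocounts). Nkx2-5 was higher by 2.57 ± 0.15, Mef2c by 3.19 ± 0.22 and Isl1 by 0.81 ± 0.13 (adjusted p = 1.81e-07, 5.77e-07 and 0.000569).

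All 28 sarcomere and contractile genes were higher in green-only than in double-negative cells (28 adjusted over the list alone; median 3.28, camera adjusted p = 4.62e-39). The same direction held for 16 of 20 core cardiac transcription factors (18 adjusted over the list alone; median 1.15, camera adjusted p = 6.79e-19), 6 of 9 first heart field genes (7 adjusted over the list alone; median 0.90, camera adjusted p = 1.13e-07) and 8 of 18 calcium handling and ion channel genes (8 adjusted over the list alone; median 0.24, camera adjusted p = 3.69e-06). BMP pathway genes were higher in 11 of 20 cases (12 adjusted over the list alone; median 0.31, camera adjusted p = 1.13e-07). Of 24 endothelial genes 14 were higher (19 adjusted over the list alone; median 0.82, camera adjusted p = 1.30e-08), a count of all genes that was 8 without double-negative A, 8 without green-only B and 7 without green-only C. With an estimated inter-gene correlation the endothelial call did not hold (adjusted p = 0.216), nor did those of cell cycle (0.112), smooth muscle (0.205), stress (0.370), mesenchyme (0.205), mitochondrial (0.370), neural (0.216) and blood genes (0.232). Cell cycle genes were lower in 18 of 27 cases (19 adjusted over the list alone; median -0.41, camera adjusted p = 1.77e-10), and pluripotency genes in 11 of 18 (11 adjusted over the list alone; median -0.80, camera adjusted p = 1.29e-08). Other lists past the threshold were those of reporter-linked (median 2.57 over 3 genes, camera adjusted p = 5.83e-06), second heart field (0.32, 0.00122), smooth muscle (0.35, 0.000994), stress and dissociation (0.50, 0.00122), mesenchyme and matrix (0.22, 0.00635), mitochondrial (0.09, 0.00430) and neural genes (-0.23, 0.00430). The second heart field median was 0.19 without double-negative A and 0.53 without double-negative C, the mesenchyme median 0.10 without green-only C, and the mitochondrial median 0.14 without green-only A. Blood genes (-0.13, 0.0112) did not pass without green-only A (-0.07, 0.138). Endoderm genes (0.19, 0.168) had a median of -0.09 without green-only A, and passed as higher without double-negative A (0.0308) or green-only B (0.00469), and at a value that rounds to 0.05 with the experiment as a block. Glycolysis genes (0.14, 0.0735) passed without green-only A (0.0250), green-only B (0.0495) or double-negative C (0.0322), after quantile normalization (0.0355) and with no filter on low values (0.0457). FGF pathway genes (-0.12, 0.0828) passed without green-only A (0.00978) and with no filter on low values (0.0394).

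**Figure D4:**
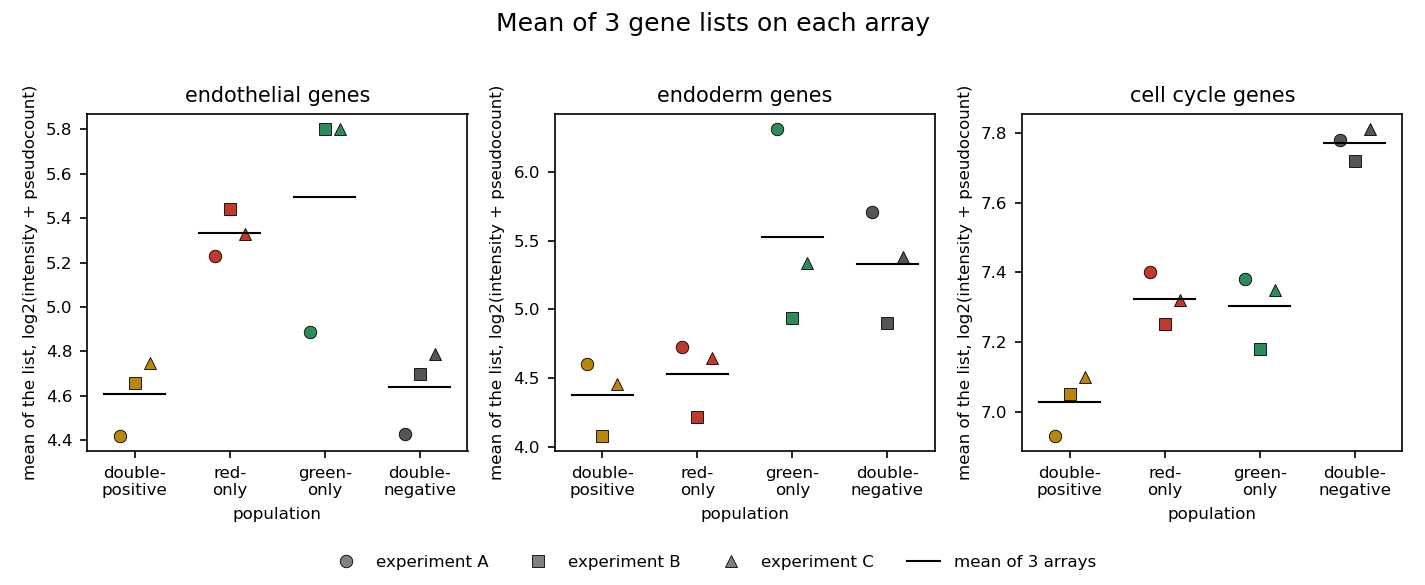
Mean log2 value of the endothelial, endoderm and cell cycle gene lists on each of the 12 arrays (vertical axis, log2 of intensity plus pseudocount; populations on the horizontal axis, points are arrays and bars the mean of 3). Endothelial means were highest in the single-reporter populations, and the endoderm mean of the green-only array of experiment A lay above those of the other green-only arrays.

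The 3 comparisons with double-negative cells overlapped. Double-positive and red-only cells shared 946 higher and 1428 lower genes, against 208 and 306 for independent lists. Double-positive and green-only cells shared 1006 higher and 1400 lower genes (178 and 275 for independent lists), and red-only and green-only cells 907 and 1162 (139 and 198). Across genes, which are not independent replicates, the fold changes correlated at 0.80, 0.89 and 0.82 with covariances of 0.187, 0.207 and 0.143. These comparisons share the same 3 control arrays. In 50 simulations of unchanged populations against shared controls the correlation was 0.50, the covariance 0.007 and the mean overlap at most 0.02 genes. The 3 control arrays could not be divided into parts of at least 2, so part of the excess may come from the shared controls.

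The red reporter's difference can also be read from separate arrays, with the green reporter absent (red-only against double-negative) or present (double-positive against green-only). Both called 208 genes higher in the red-positive cells, against 42.5 for independent lists, and 119 without double-positive A. Both called 147 genes lower (48.2 for independent lists), and 81 genes differed in opposite directions (90.8). The 147 were 57, 67 and 89 without double-positive A, B and C, and the 81 were 38 without double-positive A, 40 without double-positive B, 51 without green-only C and 126 without green-only A. The fold changes correlated at 0.39 across genes, with a covariance of 0.0441 (6.5e-06 in simulations without effects). For the green reporter, double-positive against red-only and green-only against double-negative called 410 genes higher in both, against 75.9 for independent lists, with a correlation of 0.46 and a covariance of 0.0643. They called 232 genes lower in both (96.3 for independent lists) and 159 in opposite directions (171). The 232 were 136 without double-positive A, 144 without double-positive B, 127 without red-only A and 140 without red-only C, and the 159 were 103 without double-positive B and 102 without red-only B.

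Double-positive and red-only cells were compared to ask what the green reporter adds among red-positive cells. Of 13698 genes 1656 (12.1%) differed, 813 higher and 843 lower in double-positive cells. The 5 largest increases were Myl2 (1100 ± 200 against 33.8 ± 13; log2 fold change 4.89 ± 0.28 SE, adjusted p = 1.77e-06), Myl3 (4.29 ± 0.34, adjusted p = 6.44e-06), Myh6 (3.67 ± 0.26, adjusted p = 3.81e-06), Actn2 (3.12 ± 0.29, adjusted p = 1.73e-05) and Sh3bgr (3.09 ± 0.20, adjusted p = 3.53e-06). The 5 largest decreases were the collagen gene Col3a1 (18.1 ± 6.4 against 177 ± 180; -2.62 ± 0.47, adjusted p = 0.00266), Nnat (312 ± 44 against 1760 ± 430; -2.46 ± 0.16, adjusted p = 3.40e-06), Cdh11 (-2.44 ± 0.19, adjusted p = 6.44e-06), Hsd11b2 (-2.21 ± 0.16, adjusted p = 4.22e-06) and Tnc (-1.96 ± 0.49, adjusted p = 0.0195). The SD of Col3a1 in red-only cells was as large as its mean, and its change was -1.85 without red-only A. Cdh11 in double-positive cells lay under every array median, so the size of its change is uncertain, from -2.90 to -2.19 with other pseudocounts. Tnc did not pass without red-only A (0.0872), double-positive B (0.0825) or double-positive C (0.0696), or with an intensity trend in the variance (0.0705). Nkx2-5 was higher in double-positive cells by 1.31 ± 0.15 (adjusted p = 8.58e-05). Mef2c was higher by 0.96 ± 0.22 (adjusted p = 0.0111), and by 0.81 (adjusted p = 0.0555) without red-only A. Isl1 did not differ past the threshold (-0.21 ± 0.13, adjusted p = 0.356).

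The lists higher in double-positive than in red-only cells were mostly contractile and metabolic. All 28 sarcomere and contractile genes (28 adjusted over the list alone; median 2.58, camera adjusted p = 8.33e-45), 17 of 22 mitochondrial genes (20 adjusted over the list alone; 0.51, 2.31e-18), 10 of 15 glycolysis genes (13 adjusted over the list alone; 0.58, 1.01e-09) and 9 of 18 calcium handling and ion channel genes (11 adjusted over the list alone; 0.50, 6.51e-09) were higher. The calcium handling median was 0.30 without double-positive A, the array with the highest actin 3' to 5' ratio and 18S signal. With an estimated inter-gene correlation the sarcomere, mitochondrial and calcium handling calls held, and the others in this paragraph did not, with adjusted p of 0.0872 for first heart field, 0.127 for glycolysis and for mesenchyme, 0.192 for core cardiac, 0.224 for cell cycle, 0.290 for endothelial and 0.383 for smooth muscle genes. Core cardiac transcription factors were higher in 7 of 20 cases (8 adjusted over the list alone; 0.25, 0.000101). First heart field genes had a median of 0.22 (camera adjusted p = 0.00204). Smooth muscle genes had a median of 0.51 (camera adjusted p = 0.0231), and did not pass without double-positive A (0.0812) or red-only B (0.0587). The 3 reporter-linked genes (0.96, 0.0629) passed with the experiment as a block (0.0369), and without double-positive A (0.0348), green-only A (0.0476), double-negative A (0.0475) or red-only C (0.0279). Mesenchyme and matrix genes were lower in 10 of 20 cases (10 adjusted over the list alone; -0.62, -0.39 without red-only A, 0.000140), and cell cycle genes in 10 of 27 (14 adjusted over the list alone; -0.30, 5.70e-08). Of 24 endothelial genes 7 were lower (12 adjusted over the list alone, 15 with the experiment as a block; -0.69, 1.97e-08). That count was 4 without double-positive A, red-only B or red-only C, and 17 without green-only A. The second heart field gene Foxc1 was lower (18.0 ± 0.89 against 66.2 ± 7.1; -1.66 ± 0.14, adjusted p = 7.69e-06), in a list whose median was -0.04 (camera adjusted p = 0.462). Tdgf1 was higher (192 ± 27 against 28.1 ± 9.1; 2.63 ± 0.21, adjusted p = 6.44e-06), in a pluripotency list whose median was -0.04 (camera adjusted p = 0.619).

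Double-positive and green-only cells were compared to ask what the red reporter adds among green-positive cells. Of 13698 genes 770 (5.62%) differed, 390 higher and 380 lower in double-positive cells. With the experiment as a block the count was 1282, 603 higher and 679 lower. It was 357 without double-positive A and 473 without double-positive B. The 5 largest increases were Smpx (45.8 ± 19 against 9.79 ± 1.7; log2 fold change 1.79 ± 0.19 SE, adjusted p = 0.000761), Mlf1 (1.69 ± 0.14, adjusted p = 0.000108), Tdgf1 (1.62 ± 0.21, adjusted p = 0.00139), Smyd1 (1.61 ± 0.20, adjusted p = 0.00110) and Mylk3 (1.60 ± 0.24, adjusted p = 0.00254). The 5 largest decreases were Krt18 (113 ± 51 against 783 ± 620; -2.60 ± 0.52, adjusted p = 0.0122), Cdh1 (6.49 ± 2.3 against 66.8 ± 48; -2.57 ± 0.34, adjusted p = 0.00150), Cpm (-2.56 ± 0.40, adjusted p = 0.00312), Trh (-2.56 ± 0.32, adjusted p = 0.00112) and Clic6 (-2.51 ± 0.51, adjusted p = 0.0137). Each of these 5 decreases had its highest green-only value in experiment A, as Krt18 at 1500 against 387 and 465 and Cdh1 at 122 against 39.0 and 39.5, the array in which endoderm genes were also high (mean log2 value 6.31 against 4.94 and 5.34). Without green-only A the changes of Krt18, Cdh1, Cpm, Trh and Clic6 were -1.99, -2.06, -1.98, -2.22 and -1.83, all past the threshold. Cdh1 in double-positive cells lay within the range of the array medians and there are no detection calls, so the size of its change is uncertain, from -3.01 to -2.33 with other pseudocounts. Clic6 did not pass without double-positive B (0.0555). In a test of all probe sets, the other probe set of Clic6 (mean intensity 83.7) did not pass, while that of Cpm did. With an intensity trend in the variance, Krt18 (0.0529) and Clic6 (0.0568) did not pass, nor did they in a fit of the 6 arrays alone (0.0588 and 0.0670). Nkx2-5 was higher in double-positive cells by 0.83 ± 0.15 (adjusted p = 0.00703). Mef2c was higher by 1.01 ± 0.22 (adjusted p = 0.0175), with 1.04 (0.0543) without double-positive A and 0.96 (0.0618) without double-positive B. Of the 4 other probe sets of Mef2c, 1 passed in the same direction and 3 did not pass. Isl1 did not differ past the threshold (0.10 ± 0.13, adjusted p = 0.776).

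Among the lists, 20 of 28 sarcomere and contractile genes (25 adjusted over the list alone; median 1.08, camera adjusted p = 4.90e-24) and 13 of 22 mitochondrial genes (18 adjusted over the list alone; 0.38, 1.96e-16) were higher in double-positive than in green-only cells. With an estimated inter-gene correlation neither call held (adjusted p = 0.149 and 0.0857), nor did any other of this comparison, with adjusted p of 0.0857 for calcium handling, 0.149 for endothelial, core cardiac, reporter-linked and cell cycle, 0.163 for endoderm, 0.321 for blood and 0.471 for glycolysis genes. Without double-positive A, the array with the highest actin 3' to 5' ratio and 18S signal, the counts of 20 and 13 were 10 and 7. Calcium handling (0.23, 2.76e-06), core cardiac (0.26, 0.15 without green-only A, 2.51e-05) and reporter-linked genes (0.83, 0.00562) also had higher medians. Glycolysis genes (0.25, 0.00980) did not pass without green-only A (0.10, 0.0655) or double-positive C (0.0549). Second heart field genes (0.15, 0.0954) passed with the experiment as a block (0.0482). Of 24 endothelial genes 9 were lower (18 adjusted over the list alone, 18 with the experiment as a block; -0.84, 3.16e-15). That count was 4 without double-positive A, 5 without double-positive B, green-only B or green-only C, and 19 without green-only A. Of 21 endoderm genes 5 were lower (10 adjusted over the list alone, 12 with the experiment as a block; -1.16, 4.70e-09). That count was 3 without double-positive A, double-positive B or green-only C, and 9 without green-only B, and the median was -0.53 without green-only A. Of 27 cell cycle genes 7 were lower (15 adjusted over the list alone, 11 with the experiment as a block; -0.27, 9.19e-12). That count was 1 without double-positive A, 2 without green-only A or C, and 3 without double-positive B or C. Blood genes (-0.15, 0.0234) did not pass without double-positive A (0.0561), green-only B (0.109) or green-only C (0.115), or with no filter on low values (0.111). Wnt pathway genes (-0.08, 0.0892) passed with no filter on low values (0.0434).

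Red-only and green-only cells were compared to ask how cells with one reporter differ from cells with the other. Of 13698 genes 422 (3.08%) differed, 181 higher and 241 lower in red-only cells. With the experiment as a block the count was 789, 359 higher and 430 lower. It was 210 without red-only A and 203 without red-only B. The 5 largest increases were Cdh11 (51.2 ± 7.8 against 6.25 ± 1.3; log2 fold change 2.42 ± 0.19 SE, adjusted p = 5.81e-05), Col3a1 (2.41 ± 0.47, adjusted p = 0.0145), Tgfbi (2.15 ± 0.22, adjusted p = 0.000271), Nnat (1.96 ± 0.16, adjusted p = 5.81e-05) and Foxc1 (66.2 ± 7.1 against 16.1 ± 3.7; 1.81 ± 0.14, adjusted p = 5.81e-05). The 5 largest decreases were Myl2 (33.8 ± 13 against 394 ± 160; -3.38 ± 0.28, adjusted p = 5.81e-05), Myl3 (-3.08 ± 0.34, adjusted p = 0.000414), Myh6 (-2.77 ± 0.26, adjusted p = 0.000121), Pyy (-2.48 ± 0.56, adjusted p = 0.0304) and Clic6 (-2.40 ± 0.51, adjusted p = 0.0239). Cdh11 in green-only cells lay under every array median, so the size and rank of its change are uncertain, from 2.85 to 2.17 with other pseudocounts. Col3a1 was 1.64 without red-only A (384 there against 74.5 and 73.4). Pyy and Clic6 had their highest green-only values in experiment A (588 and 451), and were -1.72 and -1.71 without that array. Pyy did not pass without red-only A (0.127), red-only B (0.105) or green-only C (0.0747), or with no filter on low values (0.0594). Clic6 did not pass without red-only A (0.0532), red-only B (0.109) or red-only C (0.0516). In a test of all probe sets, another passed for Tgfbi, Foxc1 and Myl3. No other probe set passed for Cdh11, Col3a1, Myh6 or Clic6, that of Clic6 having a mean intensity of 83.7. With an intensity trend in the variance Col3a1 (0.0649), Pyy (0.113) and Clic6 (0.0955) did not pass, nor did they in a fit of the 6 arrays alone (0.0937, 0.132 and 0.0870). None of Nkx2-5 (-0.48 ± 0.15, adjusted p = 0.126), Mef2c (0.05 ± 0.22, adjusted p = 0.958) and Isl1 (0.31 ± 0.13, adjusted p = 0.256) differed past the threshold.

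In red-only cells, 22 of 28 sarcomere and contractile genes (27 adjusted over the list alone; median -1.59, camera adjusted p = 1.05e-40) and 7 of 18 calcium handling and ion channel genes (7 adjusted over the list alone; -0.25, 2.19e-06) were lower than in green-only cells. The count of 7 was 4 without red-only A, red-only B or green-only B. First heart field (-0.30, 6.98e-05), glycolysis (-0.27, 1.73e-08) and mitochondrial genes (-0.13, 1.34e-05) were lower, and endoderm genes too (-0.96, 9.65e-08; median -0.47 without green-only A). With an estimated inter-gene correlation the calls of glycolysis (adjusted p = 0.162), mitochondrial (0.253), endoderm (0.253) and second heart field genes (0.0613) did not hold. Mesenchyme and matrix genes were higher in 8 of 20 cases (10 adjusted over the list alone; 0.33, 2.78e-08), among them Snai2 (1.34 ± 0.15, adjusted p = 0.000482) and Twist1 (53.2 ± 0.96 against 19.4 ± 6.4; 1.32 ± 0.21, adjusted p = 0.00387). Second heart field genes had a median of 0.10 (camera adjusted p = 0.00487), which was 0.17 without red-only A, 0.24 without green-only B and 0.16 without green-only C. Endothelial genes (-0.21, 0.136) passed without green-only A (-0.51, 6.61e-10), as did core cardiac (-0.11, 0.175; -0.20, 0.0164) and blood genes (-0.05, 0.364; 0.0168). Core cardiac genes also passed without red-only C (0.0371). Smooth muscle genes (-0.18, 0.0582) passed with the experiment as a block (0.0231) or after quantile normalization (0.0364), and without double-positive A (0.0361), double-positive B (0.0464), red-only A (0.0116), red-only C (0.0459) or green-only B (0.0290).

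Camera was run with a preset inter-gene correlation of 0.01, and fewer lists passed in the setting that estimates the correlation. That setting was run only without the experiment as a block, so differences between experiments stayed in the residuals it used. Whether the estimated correlation itself or another part of that setting lowered the counts was not tested. With 24 lists, the preset called 17 in double-positive, 16 in red-only and 16 in green-only cells against double-negative cells, and 10, 10 and 8 in double-positive against red-only, double-positive against green-only and red-only against green-only cells. With a correlation estimated per list these numbers were 7, 7, 8, 3, 0 and 4. For double-positive against green-only cells camera with the estimate called 0 lists, with a lowest adjusted p of 0.0857, 7 lists at an unadjusted p under 0.05, and 9 lists by fry, which tests whether a list's own genes move one way. The calls that held with the estimate in all 3 comparisons with double-negative cells were those of reporter-linked, core cardiac, second heart field, first heart field and pluripotency genes. Sarcomere and calcium handling genes held in double-positive and green-only cells, BMP pathway genes in red-only and green-only cells, and mesenchyme genes in red-only cells. Sarcomere, calcium handling and mitochondrial genes held in double-positive against red-only cells. First heart field, sarcomere, calcium handling and mesenchyme genes held in red-only against green-only cells. No endothelial, endoderm or cell cycle call held with the estimate.

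The median, mean and camera direction of a list differed in sign only in lists past no camera threshold. Apart from the case of paraxial genes already given, these were paraxial, epicardial, Wnt, Notch and mitochondrial genes in red-only and paraxial and Wnt genes in green-only against double-negative cells. They were pluripotency, primitive streak, epicardial and stress genes in double-positive against red-only cells, and smooth muscle, neural, paraxial, mesenchyme and epicardial genes in double-positive against green-only cells. In red-only against green-only cells they were reporter-linked, pluripotency, cell cycle, BMP and FGF genes, and in the interaction of the reporters smooth muscle, epicardial and Notch genes.

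Each population was also placed against the other 3. Double-negative cells were highest for 1098 genes and lowest for 749, counting genes past the threshold against each other population. Double-positive cells were highest for 308 genes (153 without double-positive A) and lowest for 139 (62 without double-positive A, 83 without double-positive B). Red-only cells were highest for 108 genes (62 without red-only A, 64 without red-only B). Green-only cells were highest for 14 genes. That number was 42 without green-only A, 9 without double-positive A, double-positive B or green-only B, and 5, 3 and 6 without red-only A, B and C. Red-only cells lay above both double-positive and double-negative cells for 318 genes, and between them, with double-positive cells above, for 246 genes. Green-only cells lay above both for 89 genes and between them for 239. Those 89 were 43 without double-positive A or B, 57 without double-positive C and 149 without green-only A, and the 239 were 137 without double-positive A. Red-only cells were lowest for 29 genes, and below both double-positive and double-negative cells for 94. Green-only cells were lowest for 1 gene and below both for 9.

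The interaction of the reporters asks whether the difference between red-positive and red-negative cells depends on the green reporter. It was the log2 fold change of double-positive against green-only minus that of red-only against double-negative cells. It differed from 0 for 1433 of 13698 genes (10.5%), above 0 for 657 and below for 776. With the experiment as a block the count was 2057, 989 above 0 and 1068 below. The 5 genes with the smallest adjusted p were Utf1 (2.73 ± 0.15 SE, adjusted p = 2.43e-06), Sfrp2 (1.81 ± 0.11, adjusted p = 4.90e-06), Hbb-y (3.74 ± 0.25, adjusted p = 9.99e-06), Nanog (2.64 ± 0.18, adjusted p = 9.99e-06) and Nefl (1.78 ± 0.13, adjusted p = 1.60e-05). All 5 were high in double-negative cells and at a similar low level in the other populations, as Nanog at 51.7 ± 12 against 3.82 ± 0.40, 4.04 ± 0.16 and 4.47 ± 0.70. For Nanog, Nefl and Hbb-y those low means lay at or under the highest array median, where differences among the 3 populations may not be measurable. The same held for 36 of the 1433 genes, and for 3 of the pluripotency genes called. Nkx2-5, Mef2c and Isl1 had interactions of -1.25 (adjusted p = 0.00263), -2.23 (0.000700) and -1.02 (0.00313). On the log2 scale their red difference was smaller among green-positive cells (0.83, 1.01 and 0.10) than among green-negative cells (2.09, 3.24 and 1.12). In intensity units, by the group means given above, only that of Isl1 was smaller among green-positive cells, so the result depends on the scale. Endothelial genes were below 0 in 17 of 24 cases (22 adjusted over the list alone; median -1.63, camera adjusted p = 7.84e-17), a call that did not hold with an estimated inter-gene correlation (adjusted p = 0.0993). Of 24 lists camera called 14 for the interaction with the preset and 7 with the estimate, those of reporter-linked, core cardiac, second and first heart field, pluripotency, mesenchyme and BMP pathway genes. Core cardiac transcription factors were below 0 in 11 of 20 cases (13 adjusted over the list alone; -0.98, 2.27e-12) and BMP pathway genes in 11 of 20 (14 adjusted over the list alone; -0.66, 1.49e-09). Pluripotency genes were above 0 in 10 of 18 cases (11 adjusted over the list alone; 0.83, 7.86e-10). List tests of the interaction were chosen after the gene values had been seen.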

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

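The tests of the endothelial pattern were chosen after the result was seen, while the interaction test and its regroupings were planned, though the second draw was not. The difference between red-positive and red-negative cells differed between green-positive and green-negative cells for 1433 genes, by a test of the difference itself. The 5 genes with the smallest adjusted p were Utf1 (2.73 on the log2 scale), Sfrp2 (1.81), Hbb-y (3.74), Nanog (2.64) and Nefl (1.78). Those 5 were high in double-negative cells and low in each other population, and for 3 of them, Hbb-y, Nanog and Nefl, the low means lay at or under the highest array median, so a further decrease might not have been measured. On the log2 scale, Nkx2-5 (-1.25), Mef2c (-2.23) and Isl1 (-1.02) had a smaller red difference among green-positive cells, while in intensity units only Isl1 did. The log2 interactions of these genes stayed past the threshold without each single array, with adjusted p of 0.000626 to 0.00943, 8.96e-05 to 0.00288 and 0.00120 to 0.00934. Of 100 regroupings of arrays within the experiments, the real one included, 1 called as many genes, the real one, and the highest other called 416. A first draw of 100, which could hold one grouping more than once, had 2 as large, the other calling 2234 genes, and the draw with each grouping once was made after that had been seen. Regrouping puts the differences between populations into the spread within groups and into the contrast, so neither draw tests the interaction alone, and whether it arose by chance is not decided by them.

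Endothelial genes differed in the same test for 17 of 24 genes, all below 0, though the list's camera call did not hold with an estimated inter-gene correlation (adjusted p = 0.0993). Of the 24 genes, 10 were above both double-positive and double-negative cells in a single-reporter population, 6 in red-only, 7 in green-only and 3 in both, a number that was 5 without double-positive A and 20 without green-only A. A mixture of double-positive and double-negative cells of average make-up lies between its parts, so those 10 genes argue against such mixing as the cause. They cannot speak on mixing with a subset of either population. Endothelial cells inside the red-only and green-only gates stay open: of the 10 most abundant endothelial genes 9 had means in both single-reporter populations above both others, but this count restates the pattern and is no evidence for such cells. Kdr averaged 145, 385, 386 and 108 in double-positive, red-only, green-only and double-negative cells, Ramp2 105, 283, 319 and 109, and the exception was Flt1 (32.5, 35.3, 53.4 and 35.7), while a sort on the reporters would not remove endothelial cells that carry one; Sox17 is also in the endoderm list, and reporter activity in endothelial progenitors, the biological alternative, was not tested and also stays open.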

How the results depend on the processing

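Counts of list genes, of genes placed between populations and of genes called in 2 comparisons, with arrays left out, were chosen after seeing the data, and the alternatives below were planned. No named gene or list past its threshold changed direction. The endoderm median of green-only against double-negative, 0.19 and not past it, became -0.09 without green-only A. The order of counts below is double-positive, red-only and green-only against double-negative, double-positive against red-only, double-positive against green-only, and red-only against green-only.

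With the experiment as a block double-positive against green-only called 1282 genes and red-only against green-only 789. The total counts of the other comparisons, the F-test and the interaction, and those of lists called, stayed within 1.5 times. Interaction genes above 0 rose from 657 to 989, just past 1.5 times. Counts inside lists moved more, as for endothelial genes from 7 to 15 in double-positive against red-only and from 9 to 18 in double-positive against green-only, and for endoderm genes from 5 to 12 in the latter. With every probe set on its own the first 4 comparisons called 7134, 5028, 4528 and 2523 and the F-test 7071, with more features tested. With only the 6 arrays compared the last 2 comparisons called 258 and 199, with fewer degrees of freedom. At least 2-fold changes numbered 714, 459, 378, 274, 153 and 120, and 388 for the interaction, by construction fewer. With an estimated inter-gene correlation camera called 7, 7, 8, 3, 0 and 4 lists, the 0 with 7 lists at an unadjusted p under 0.05 and 9 by fry. Whether the estimated correlation itself or another part of that setting lowered the counts was not tested.

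Leaving out single arrays or whole experiments gave 2734 to 4577, 1766 to 3586, 1295 to 3169, 614 to 1956, 186 to 775 and 51 to 474 genes, 2348 to 4809 in the F-test and 263 to 1700 for the interaction. The lowest values came without experiment B or C. Leaving out experiment A also leaves 2 arrays per group, yet 36 named values were lost without it, against 124 without B and 128 without C. The number of arrays alone thus does not account for the lowest values. Among single arrays, double-positive A (357) and B (473) moved the count of double-positive against green-only, and red-only A (210) and B (203) that of red-only against green-only, by more than 1.5 times; the cause was not tested. Lists called ran from 14 to 18, 14 to 17, 16 to 18, 9 to 11, 9 to 10 and 8 to 11.

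Of 451 named values 414 passed the threshold. Those lost numbered 0 with the block and 0 among the 431 that the stricter filter kept. The other 20 were not tested with that filter, 14 of them past the threshold. Either pseudocount or quantile normalization lost 7, every probe set on its own 12 and no filter 27. An intensity trend together with the robust option lost 29. A fit of 6 arrays lost 51 of 446, since it gives no interaction and so leaves out 5. Single arrays lost 14 (green-only A) to 45 (red-only B), and experiments A, B and C 36, 124 and 128. The block gained 16 named values, and of 144 list results it gained 5 and lost 0. For the interaction it called 16 lists in place of 14. Low signal limits 33 named values with a group at or under the highest array median, and 111 named calls had no other probe set past the threshold.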

Other observations

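The tests of the endoderm and cell cycle patterns below were chosen after the result was seen, and for both patterns a first version of a test was replaced after its outcome was known. The counts over other splits were planned, apart from the second draw of regroupings.

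Endoderm genes were high in the green-only array of experiment A. Over 21 genes the median difference of experiment A from the mean of B and C was 1.39 on the log2 scale in green-only cells, against 0.22, 0.21 and 0.29 in double-positive, red-only and double-negative cells (permutation p across genes 7e-05, 5e-05 and 0.00069, genes not being independent), which argues against a difference shared by all populations of that experiment. In green-only A, 17 of the 21 genes lay above every double-negative array and above green-only B and C, as did 18.3% of all genes. This argues against carried-over double-negative cells of average make-up. It cannot speak on a subset of double-negative cells, since the arrays measured only their average. Endoderm cells inside the gate stay open as a source: 10 of the 10 most abundant endoderm genes were higher in green-only A than in B and C, but this count restates the pattern and is no evidence for such cells, and a gate on the reporters would not remove such cells if they carried the green one. Green-only means over 3 arrays were 687 for Spink1, 384 for Cldn6 and 351 for Rbp4, against 391, 464 and 216 in double-negative cells; Sox17 and Foxa2 are also in other lists, and no biological explanation was tested.

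Of 27 cell cycle genes 10 were lower in double-positive than in red-only and 7 than in green-only cells (the 7 were 1 without double-positive A, 2 without green-only A or C and 3 without double-positive B or C), and neither list call held with an estimated inter-gene correlation (adjusted p = 0.224 and 0.149). If more double-negative cells of average make-up in the single-reporter sorts were the cause, pluripotency genes would need a like share of such cells. The share needed by 11 pluripotency genes had a median of 1.45% in red-only and 1.37% in green-only cells. For 25 cell cycle genes it was 28.5% and 26.4% (permutation p across genes 0.014 and 0.046, genes not being independent). This argues against carry-over of such average cells, although single pluripotency genes needed up to 19.8% and 43.9%. Carry-over of a subset of double-negative cells is not covered by this comparison. A difference in proliferation between the populations, the biological explanation, was not tested and may account for the lower cell cycle genes.

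For each pairwise comparison, the real split was 1 of the 4 splits that part all 3 experiment pairs, too few for a share under 0.05. The real splits called 4317, 3228, 2842, 1656, 770 and 422 genes, in the order double-positive, red-only and green-only against double-negative, double-positive against red-only, double-positive against green-only, and red-only against green-only. The highest other of the 4 called 0, 0, 3, 0, 0 and 0 by limma, and at most 316, 356, 839, 346, 449 and 459 genes at an unadjusted p under 0.05 (real 5381, 4584, 4312, 3310, 2526 and 2056). The 6 splits that part 1 pair called at most 2, and at most 516, 777, 1557, 705, 1217 and 1532 at an unadjusted p under 0.05. In every split but the real one each group held arrays of both populations. Their difference then went partly into the spread within groups, so few gene calls there say little about chance. For lists, camera called 17, 16, 16, 10, 10 and 8 in the real splits and up to 10, 11, 11, 8, 7 and 6 in the others of the 4. The 6 splits that part 1 pair called up to 12, 10, 13, 10, 9 and 8, as many as the real split in 1 split each for double-positive against red-only and red-only against green-only. Camera at the preset correlation thus called many lists under the other splits. Each of these set 2 arrays of a population and 1 of the other against the reverse, so part of the real difference remained. The list counts therefore do not show how many lists would be called without a difference.

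For the F-test, 1 of 100 regroupings within the experiments, the real one, called as many genes as the real 4429. The highest other called 2177. A share of 1 in 100 is the smallest this draw can give, so it argues against chance but does not exclude it. Those counts come from the second draw, made after the first had been seen. The first draw of 100 regroupings also had 1 as large, with a highest other of 3331.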
